A study of Homo sapiens with 10 samples.

How the data were processed

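RNA was measured in MM.1S cells, a human multiple myeloma cell line, 48 h after infection with lentivirus carrying a short hairpin RNA, per the labels' protocols. The 10 arrays form 5 groups of 2: a hairpin against luciferase as the control (shLuc), 2 hairpins against HDAC3 (shHDAC3#1 and shHDAC3#2) and 2 hairpins against DNMT1 (shDNMT1#1 and shDNMT1#2). The labels call the shLuc arrays the control of the HDAC3 hairpins. Whether the DNMT1 arrays were infected, hybridized and normalized together with them is not given in the sources used here. The labels do not say that the replicates of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

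The deposited values are log2 signals of 54675 probe sets of an Affymetrix 3' expression array, made with RMA, per the submitters' processing notes. RMA corrects the background, quantile-normalizes probes between arrays and summarises each probe set. Its software version, and whether all arrays went through it in 1 run, are not given in the sources used here. The log2 scale was taken from the values, which ran from about 2 to 14 in each array. RMA values near the background change little with the amount of RNA, so that changes of dim transcripts can be understated. The number of arrays, not a count of molecules, limits the precision.

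Probe sets were named through the platform annotation. A single gene symbol was given for 41097 probe sets, several for 1801 and none for 11777, and the last 2 kinds were named for no gene. Of those with 1 symbol, 41037 matched the RefSeq gene table of GRCh38.p14 by gene ID, which left every one of their symbols as it was. That table served for names only, and no coordinates are given. Each of 19775 genes was represented by its probe set with the highest mean over the 10 arrays, and 10523 of these genes had more than 1 probe set. No dim probe set was removed. Control probe sets entered no test.

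Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on level). One model held all 5 groups, so that they shared one estimate of the spread between replicates, with 5 residual degrees of freedom per gene. A knockdown was the mean of its 2 hairpins minus shLuc. The difference between the knockdowns and the difference between hairpins of 1 target were contrasts of the same model. Tests were two-sided, p-values were adjusted with the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. Errors given as SE are limma's standard errors of the log2 change, with n = 4 knockdown and 2 control arrays unless stated otherwise. The model's error does not hold the variation between hairpins of 1 target.

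The 22 gene lists, the 6 lists of markers of other cell types, the tests and the rule for naming genes were set before the data were examined. Of 530 entries of the gene lists, 484 had a measured gene; the other entries were not analysed here. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted with the Benjamini-Hochberg method over the 22 lists of a comparison, and again with a correlation estimated from the residuals. The median of a list was also placed among 10000 random lists of the same size drawn from the same 20 bins of mean level. Named genes were both targets; the 10 largest increases and 10 largest decreases of each knockdown among called genes that moved the same way with an unadjusted p under 0.05 for each hairpin; up to 4 called members of each list with the largest change, together with MYC, CDKN1A, IRF4 and PRDM1; the 5 highest and 5 lowest genes shared by the knockdowns, ranked by the smaller change; the 5 highest and 5 lowest in the difference between the knockdowns; and the 3 highest and 3 lowest between hairpins of 1 target. Symbols starting with LOC were left out.

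Both knockdowns were set against the same 2 control arrays. Unchanged groups against such controls were therefore simulated 1000 times from each gene's moderated residual SD, to give the chance value of each measure of shared response, and pairs of unchanged hairpins likewise. The draws were independent between genes and held no variation between hairpins or cultures. The gene test was checked on simulated data with the real means and moderated residual SDs of the 19775 genes, in which 100 genes changed by 0.5 and 100 by 1 in a knockdown. It recovered 89% and 100% of these in the simulated HDAC3 comparison, and 85% and 100% in the simulated DNMT1 comparison. Unchanged genes made up 12 of 201 and 10 of 195 calls. The simulated change was the same for both hairpins of a target, so these rates leave out any variation between hairpins.

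The alternatives were a filter on dim probe sets; the mean of a gene's probe sets; leaving out probe sets that can cross-hybridize; a further quantile normalization; centring each array on its median; eBayes without the trend; array weights; only the arrays of a comparison; both hairpins as 1 group; the hairpin as a random block; either hairpin alone; the replicate number as a block; each array left out in turn; and, for lists, an estimated correlation and fry. A fit with the SD of each array's log2 values as a covariate was added after seeing the data.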

Results

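Gene expression was measured in MM.1S myeloma cells after knockdown of HDAC3, a histone deacetylase of the NCoR and SMRT co-repressor complexes, or of DNMT1, which copies DNA methylation to newly replicated DNA. Each knockdown had 2 hairpins with 2 arrays each (n = 4), and the luciferase hairpin shLuc served as control (n = 2). Over the 19775 genes, arrays of 1 group correlated with Pearson's r between 0.9937 and 0.9963, and arrays of different groups with r between 0.9748 and 0.9937. No pair of replicates was a duplicate: the root mean square difference between them was 0.159 to 0.209 on the log2 scale.

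The arrays differed in the spread of their values. The SD of the log2 values was 1.943 and 1.929 in the shLuc arrays and lay between 1.843 and 1.915 in the 8 knockdown arrays. The first principal component, with 36.9% of the variance, placed the shLuc arrays at -34.4 and -20.8 and the shDNMT1#2 arrays at 19.1 and 19.6. The difference between the 3' and 5' probe sets of ACTB, a measure of RNA integrity, averaged 1.00 (log2) in shHDAC3#1 and 0.725 in shLuc, with 0.71 to 0.74 in the other groups.

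**Figure D1:**
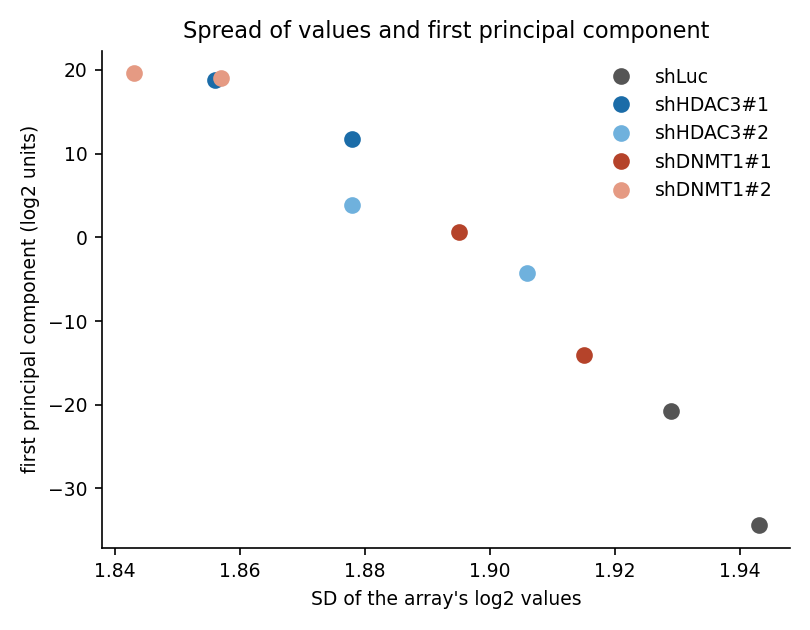
SD of the log2 values of each array (x axis) against its first principal component over 19775 genes (y axis, log2 units), 1 point per array, coloured by group. The 2 shLuc arrays have the largest SDs, 1.943 and 1.929, and the lowest components, -34.4 and -20.8.

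The targeted transcripts were examined first. HDAC3 fell to 44.2% of control in HDAC3 knockdown (log2 change -1.18 ± 0.16 SE, adjusted p = 1.2e-05), with log2 changes of -1.09 for shHDAC3#1 and -1.26 for shHDAC3#2. All 4 HDAC3 arrays, at 5.52 to 5.97, lay below both shLuc arrays, at 7.26 and 6.61. DNMT1 fell to 19.1% of control in DNMT1 knockdown (log2 change -2.39 ± 0.10 SE, adjusted p = 9.5e-12), by -2.53 and -2.24 for the 2 hairpins. DNMT1 also fell in HDAC3 knockdown, to 52.7% of control (log2 change -0.92 ± 0.10 SE, adjusted p = 1.6e-06), by -1.20 with shHDAC3#1 and -0.65 with shHDAC3#2. HDAC3 was not called in DNMT1 knockdown (log2 change -0.36 ± 0.16 SE, adjusted p = 0.11). It was called there with shDNMT1#2 alone (log2 change -0.60, adjusted p = 0.019), without shDNMT1#1 replicate 1 (-0.50, adjusted p = 0.012), and without shLuc replicate 2 (-0.69, adjusted p = 0.015). Each target was read by 1 probe set, of the kind that can cross-hybridize. Leaving out such probe sets therefore removed both targets and could not check their changes. With the hairpin as a random block, which counts the difference between hairpins as error, neither HDAC3 (adjusted p = 0.11) nor DNMT1 (adjusted p = 0.093) was called in HDAC3 knockdown, nor was either with the array SD as a covariate, chosen after seeing the data (-0.98, adjusted p = 0.36; -0.63, adjusted p = 0.31).

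**Figure D2:**
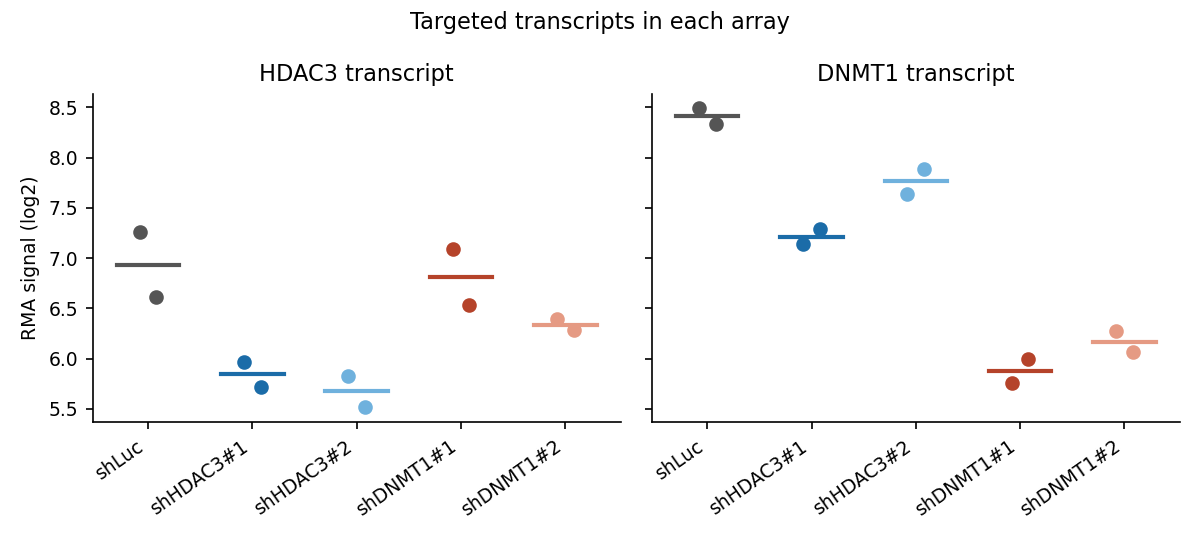
RMA signal (log2, y axis) of the HDAC3 and DNMT1 transcripts in each of the 10 arrays by group (x axis); points are arrays and lines are means of 2 arrays. HDAC3 lies at 5.52 to 5.97 in the arrays of its own hairpins, and DNMT1 is lower than in shLuc under all 4 hairpins.

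The first comparison asked which transcripts changed when HDAC3 was knocked down. At the preset correlation, the lists of cell division, DNA replication, DNA methylation, endoplasmic reticulum folding and antigen presentation were called lower, each with an adjusted p = 0.18 with an estimated correlation. More genes fell than rose. The largest decreases found with both hairpins were those of GALNT3, which starts mucin-type O-glycosylation (log2 change -1.93 ± 0.12 SE, 3.81-fold), the mitotic gene DEPDC1 (-1.93 ± 0.11), the H2A.Z chaperone ANP32E (-1.79 ± 0.09) and RPN2, a subunit of the oligosaccharyltransferase (-1.77 ± 0.08). UAP1, which makes UDP-N-acetylglucosamine (-1.74), the lymphocyte signalling protein THEMIS (-1.74), galectin-1 (LGALS1, -1.72), KLHL5 (-1.68), UHRF1, which brings DNMT1 to replicated DNA (-1.68), and TMEM45A (-1.67) followed. The largest increases were those of OSTM1, a partner of a lysosomal chloride transporter (1.84 ± 0.13, 3.57-fold), the nucleolar protein RRP1B (1.35 ± 0.11), C11orf54 (1.24 ± 0.10) and CLDND1 (1.01 ± 0.11). PALS1 (0.82), the ERK phosphatase DUSP5 (0.80), CFL2 (0.79), RNF149 (0.79), the nuclear RNA MALAT1 (0.71) and WASF3 (0.69) rose by less. Each gene was read by its brightest probe set, and others of the same gene could disagree. In HDAC3 knockdown the other probe sets of OSTM1 lay at 1, 0.94 and 0.33, the second of these at a mean of 5.08 against 5.37 for the brightest. Those of KLHL5 lay between -1.09 and 0.15, those of DEPDC1 between -1.83 and -1.03, that of PALS1 at 0.18, and those of CFL2 at 0.14 and 0.30. Those of C11orf54 were at 1.17 and 0.19 and that of GALNT3, at a mean of 3.23, at 0.08. A second RRP1B probe set, at a mean of 7.41, was at 0.16, and the 11 other MALAT1 probe sets lay between 0.06 and 0.87. In all, 3801 of 19775 genes were called, of which 784 rose and 3017 fell; 6 rose and 164 fell at least 2-fold.

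Among the fixed lists, the G2/M and mitosis genes had 29 of 36 measured members lower and none higher, with a median log2 change of -0.73 (camera, adjusted p = 1.4e-21; adjusted p = 0.18 with an estimated correlation). Adjusted over the list alone, 30 fell. The spindle genes ASPM (-1.33), DLGAP5 (-1.24), NUF2 (-1.02) and HMMR (-1.02) changed most. Of the DNA replication and S phase genes, 30 of 38 fell, 32 adjusted over the list alone, and 0 rose, with a median of -0.57 (adjusted p = 1.6e-20; adjusted p = 0.18 with an estimated correlation). They included the ribonucleotide reductase subunit RRM2 (-1.07), the replicative helicase subunits MCM6 (-0.89) and MCM5 (-0.87), and the polymerase POLA1 (-0.85). The falls were larger with shHDAC3#2 than with shHDAC3#1, with medians of -1.05 and -0.19 for the G2/M list and -0.71 and -0.40 for the S phase list, and RRM2 at -1.92 and -0.22. Between these hairpins the S phase list was tested after the result was seen (camera at the preset correlation, unadjusted p = 9.2e-11). The G2/M list was not tested between them. In the DNA methylation machinery 12 of 15 genes fell, 12 adjusted over the list alone, with UHRF1, MBD2 (-0.95), DNMT1 and the remodeller HELLS (-0.91) in the lead (adjusted p = 4.5e-08; adjusted p = 0.18 with an estimated correlation). Without probe sets that can cross-hybridize, MBD2 was left with 1 at a mean of 2.86, too dim to read a change (0.00). The other HELLS probe sets lay between -0.33 and 0.05, among them one at -0.3 with a mean of 6.52, against 6.94 for the brightest.

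The chaperones and unfolded protein response genes of the endoplasmic reticulum fell in 18 of 26 cases, 19 adjusted over the list alone, among them PDIA4 (-1.14), HYOU1 (-0.92), DNAJC3 (-0.86) and SEL1L (-0.84); the list's median was -0.37 (adjusted p = 3.5e-11; adjusted p = 0.18 with an estimated correlation). PDIA4 was at -1.93 with shHDAC3#1, the group whose ACTB difference was 1.00, and at -0.34 with shHDAC3#2, and the list had medians of -0.47 and -0.29. Antigen presentation genes fell in 14 of 20 cases, the same number adjusted over the list alone, where 2 also rose. HLA-DPA1 (-1.03), HLA-DRA (-0.79), HLA-DMA (-0.74) and HLA-B (-0.61) led that list (adjusted p = 1.1e-07; adjusted p = 0.18 with an estimated correlation). HLA-DRA was at -1.26 with shHDAC3#1 and -0.32 with shHDAC3#2, and the list had medians of -0.57 and -0.23. Dimmer probe sets of HLA-DPA1 were each at -0.12, while that of HLA-DRA was at -1.53 and those of HLA-B at -0.29 and -0.45. Cholesterol synthesis genes fell in 9 of 19 cases, 11 adjusted over the list alone, such as SC5D (-1.39), the SREBP regulator INSIG1 (-0.87), HMGCS1 (-0.82) and LSS (-0.81) (adjusted p = 2e-05; adjusted p = 0.18 with an estimated correlation). Without probe sets that can cross-hybridize, SC5D was left with 1 at a mean of 3, too dim to read a change (0.02). Glycolysis genes fell in 8 of 18 cases, 8 adjusted over the list alone, including ENO2 (-0.67) and LDHA (-0.65) (adjusted p = 0.00046; adjusted p = 0.27 with an estimated correlation). Polyadenylated histone genes fell in 5 of 9 cases, 5 adjusted over the list alone, with H1-10 at -0.79 and H1-2 at -0.67 (adjusted p = 0.0033; adjusted p = 0.27 with an estimated correlation). That list had a median of -0.52 with shHDAC3#1 and was not called with shHDAC3#2 (median -0.02, adjusted p = 0.17).

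A further 4 lists were called lower, and each of their calls was lost after a further quantile normalization. Proteasome subunits fell in 15 of 25 cases, 18 adjusted over the list alone, including PSMA1 (-0.78) and PSMC6 (-0.77) (adjusted p = 2.3e-08; adjusted p = 0.32 with an estimated correlation). Plasma cell and myeloma genes fell in 10 of 24 cases and 1 rose, against 12 and 1 adjusted over the list alone; SLAMF7 (-0.81), SEC11C (-0.65), MZB1 (-0.57) and ITGB7 (-0.43) led (adjusted p = 0.0012; adjusted p = 0.33 with an estimated correlation). Of these, MZB1 (0.10) and ITGB7 (0.03) were not lower with shHDAC3#2. The plasma cell regulators IRF4 (-0.09, adjusted p = 0.46; 0.18, adjusted p = 0.034, after a further quantile normalization) and PRDM1 (0.02, adjusted p = 0.92) were not called. The p53 target list had 10 lower and 2 higher members of 24, or 11 and 3 adjusted over the list alone (adjusted p = 0.024; adjusted p = 0.43 with an estimated correlation). Its lower members were led by TP53INP1 (-1.16; a second probe set at -0.16) and the death receptor gene FAS (-0.64; 0.05 without probe sets that can cross-hybridize, from 1 at a mean of 4.59), while CDKN1A, which encodes the inhibitor p21, rose by 0.29 (adjusted p = 0.01), with shHDAC3#1 (0.59) and not with shHDAC3#2 (-0.01). The heat shock list had 3 lower and 1 higher member of 12, or 7 and 1 adjusted over the list alone (adjusted p = 0.028; adjusted p = 0.34 with an estimated correlation); HSPE1 rose by 0.66 and HSPB1 fell by 0.44. With shHDAC3#2 the plasma cell (adjusted p = 0.054), p53 (adjusted p = 0.091) and heat shock lists (adjusted p = 0.29) were not called.

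Of the 12 called lists, 6 had a median outside the central 95% of random lists of the same level. The cholesterol synthesis, glycolysis, proteasome, plasma cell, p53 and heat shock lists lay within it, so their medians were not unusual for genes of their level. The other 10 of the 22 lists were not called in HDAC3 knockdown. Counting members called lower and higher, these were the NCoR/SMRT and HDAC genes (5 and 1 of 14), MYC and ribosome biogenesis genes (6 and 2 of 31), cyclin-dependent kinase inhibitors and the RB family (4 and 2 of 10), interferon-stimulated genes (7 and 1 of 34), and cancer-testis genes (2 and 1 of 31). They were also imprinted genes (4 and 1 of 18), ATF4 targets (7 and 0 of 27), BCL2 family and IAP genes (3 and 1 of 18), NF-kB targets (4 and 0 of 18), and IL-6, JAK and STAT3 genes (3 and 1 of 17). Within them, the NCoR/SMRT subunit TBL1XR1 fell by 1.19, the cell-cycle gene RBL2 by 0.94, the imprinted gene PEG10 by 0.88, the apoptosis gene PMAIP1 by 0.86 and the NF-kB inhibitor TNFAIP3 by 1.09. MYC was not called (0.07, adjusted p = 0.56), being lower with shHDAC3#1 (-0.34, adjusted p = 0.0076) and higher with shHDAC3#2 (0.47, adjusted p = 0.00075).

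The share of lower genes among those called was 79.4%, and 55.6% (1955 higher and 2451 lower) after a further quantile normalization, 88.7% after centring arrays on their medians, and 97% (43 higher and 1367 lower) without shLuc replicate 1. Requiring both hairpins left 2415 genes, shHDAC3#2 alone, without the group whose ACTB difference was 1.00, called 2146, leaving out probe sets that can cross-hybridize gave 2501, both hairpins as 1 group left 362, the hairpin as a random block left 73, the array SD as a covariate left 114, and leaving out shLuc replicate 1 left 1410 in all.

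The comparison of DNMT1 knockdown with control asked the same question of the methyltransferase. The cell division and DNA replication lists were called lower and the interferon-stimulated list higher at the preset correlation, each with an adjusted p = 0.18 with an estimated correlation. CDKN1A rose, and the plasma cell regulators PRDM1 and IRF4 fell. After DNMT1 itself, the largest decreases found with both hairpins were those of the desmosome gene PKP2 (-1.94 ± 0.12 SE, 3.83-fold), PLEKHA3 (-1.83 ± 0.14), AIDA (-1.81 ± 0.10) and RNF168, a ubiquitin ligase of the DNA damage response (-1.75 ± 0.12). ABHD3 (-1.75), HSD17B12, an enzyme of fatty acid elongation (-1.68), the cell-cycle repressor E2F8 (-1.67), EVI2B (-1.63) and the cytokinesis gene RACGAP1 (-1.63) also fell. With shDNMT1#2 and shDNMT1#1, AIDA was at -3.26 and -0.35, ABHD3 at -2.79 and -0.71, and HSD17B12 at -3 and -0.36. The largest increases were those of OSTM1 (1.82 ± 0.13, 3.52-fold), the interferon-induced TRIM22 (1.79 ± 0.12), the chemokine CXCL10 (1.45 ± 0.12), C11orf54 (1.36 ± 0.10), CDKN1A (1.15 ± 0.08) and RRP1B (1.13 ± 0.11). Other probe sets lay at 1.07, 0.83 and 0.40 for OSTM1, 1.26 and 0.15 for C11orf54, 0.25 for RRP1B, -1.03 for PKP2, -0.91 and 0.11 for PLEKHA3 and, at a mean of 4.36, -0.02 for RNF168. Those of HSD17B12, at means up to 4.26, lay between -0.14 and 0.26. PLK2 (0.95), LAMP3 (0.91), the tryptophan-degrading enzyme TDO2 (0.90) and CFL2 (0.86) rose by less. Some increases were uneven as well. With shDNMT1#2 and shDNMT1#1, CXCL10 was at 2.31 and 0.58, PLK2 at 0.37 and 1.54, and CFL2 at 1.31 and 0.41. The mean CXCL10 signal was 5.12 in shLuc, 4.81 in shHDAC3#1 and 6.21 in shHDAC3#2. In all, 3992 genes were called, of which 1317 rose and 2675 fell; 6 rose and 154 fell at least 2-fold.

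The G2/M and mitosis list had 31 of 36 members lower, 32 adjusted over the list alone, and none higher, with a median of -0.77 (camera, adjusted p = 6.7e-29; adjusted p = 0.18 with an estimated correlation). The cyclins CCNA2 (-1.47) and CCNB1 (-1.22), their kinase CDK1 (-1.27) and ASPM (-1.20) changed most. DNA replication and S phase genes fell in 27 of 38 cases, 27 adjusted over the list alone, with a median of -0.55 (adjusted p = 4.6e-20; adjusted p = 0.18 with an estimated correlation). The medians with shDNMT1#1 and shDNMT1#2 were -0.44 and -1.09 for the G2/M list and -0.35 and -0.73 for the S phase list, differences that were not tested. Of the S phase genes, POLA1 (-1.04), RRM2 (-1.01; -0.10 with shDNMT1#1) and POLE2 (-0.96) were among those that fell. In the DNA methylation machinery 11 of 15 genes fell, 11 adjusted over the list alone: beside the target, UHRF1 (-1.61), its paralog UHRF2 (-0.74) and MBD2 (-0.70) were the largest (adjusted p = 3.1e-08; adjusted p = 0.19 with an estimated correlation). Interferon-stimulated genes were the only list called higher, with 7 members higher and 3 lower of 34, or 14 and 3 adjusted over the list alone (adjusted p = 0.0088; adjusted p = 0.18 with an estimated correlation). TRIM22 and RSAD2 (0.46) rose, and SAMD9 (-0.75, with a second probe set at 0.00) and the RNA sensor IFIH1 (-0.54) fell. RSAD2 was also at 0.40 in HDAC3 knockdown, and its second probe set was at 0.18 in DNMT1 knockdown. With shDNMT1#1, 2 members of the list were higher and 1 lower (median 0.14, camera, adjusted p = 0.014). With shDNMT1#2, 11 were higher and 3 lower (median 0.21, camera, adjusted p = 0.031). Polyadenylated histone genes fell in 5 of 9 cases, 5 adjusted over the list alone, led by H2BC12 (-0.83) and H2AZ1 (-0.57) (adjusted p = 0.0088; adjusted p = 0.45 with an estimated correlation).

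The plasma cell and myeloma list held 10 lower and 4 higher genes of 24, or 10 and 6 adjusted over the list alone (adjusted p = 0.0088; adjusted p = 0.5 with an estimated correlation). The receptor gene TNFRSF17, which encodes BCMA (-1.06 ± 0.08 SE, 2.08-fold), SLAMF7 (-0.77), PRDM1 (-0.73) and IRF4 (-0.57) fell, though dimmer probe sets of PRDM1 lay at -0.37 and -0.12 and dimmer ones of IRF4 at -0.16 and 0.33. Cholesterol synthesis genes fell in 6 of 19 cases, or 11 lower and 1 higher adjusted over the list alone, including HMGCS1 (-1.12) and MSMO1 (-1.02) (adjusted p = 0.00097; adjusted p = 0.35 with an estimated correlation). Proteasome subunits fell in 8 of 25 cases, 9 adjusted over the list alone, such as PSMC6 (-0.60) (adjusted p = 1.3e-05; adjusted p = 0.48 with an estimated correlation). Glycolysis genes fell in 7 of 18 cases, 9 adjusted over the list alone, led by hexokinase HK2 (-0.68; a second probe set at 0.16) (adjusted p = 0.0088; adjusted p = 0.45 with an estimated correlation). The heat shock list had 4 lower genes, with HSPH1 at -0.66 and DNAJB1 at -0.61, and 1 higher of 12, or 8 and 1 adjusted over the list alone (adjusted p = 0.0088; adjusted p = 0.45 with an estimated correlation). The MYC and ribosome biogenesis list had 6 lower and 1 higher of 31, or 7 and 1 adjusted over the list alone, with MYC itself at 0.10 (adjusted p = 0.34) (list adjusted p = 0.032; adjusted p = 0.63 with an estimated correlation). The endoplasmic reticulum list had 7 lower and 1 higher of 26, or 9 and 1 adjusted over the list alone, with DNAJB9 (-0.66) and XBP1 (-0.54; a dimmer probe set at 0.18) lower (adjusted p = 0.042; adjusted p = 0.63 with an estimated correlation). With shDNMT1#1 the heat shock list was not called (median -0.02, adjusted p = 0.52), and with shDNMT1#2 the MYC (adjusted p = 0.42) and endoplasmic reticulum lists (adjusted p = 0.1) were not. These 7 lists were not called after a further quantile normalization, under which the medians of the MYC (0.06), endoplasmic reticulum (0.05), proteasome (0.04) and plasma cell lists (0.02) turned positive.

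Of the 12 called lists, 5 had a median outside the central 95% of random lists of the same level. The remaining 10 lists were not called in DNMT1 knockdown. Counting lower and higher members, they were the p53 targets (4 and 2 of 24), the NCoR/SMRT and HDAC genes (4 and 1 of 14), kinase inhibitors and the RB family (5 and 2 of 10), cancer-testis genes (2 and 2 of 31) and imprinted genes (3 and 1 of 18). They were also ATF4 targets (8 and 2 of 27), BCL2 family and IAP genes (3 and 1 of 18), NF-kB targets (1 and 0 of 18), IL-6, JAK and STAT3 genes (2 and 1 of 17), and antigen presentation genes (2 and 4 of 20). CDKN1B, which encodes p27, fell by 0.99 and RB1 by 0.86, while the IL-6 receptor subunit IL6ST fell by 1.37. Of the other IL6ST probe sets, 3 brighter ones lay between -0.93 and -0.68 and dimmer ones between -0.05 and 0.10. HDAC9 fell by 1.04, while dimmer probe sets lay between -0.43 and 0.07, and the cancer-testis gene MAGEB1 rose by 0.39.

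The share of lower genes among those called was 67.0%, and 53.8% (2295 of 4263 genes) after a further quantile normalization or 85.4% (3062 of 3586) after centring arrays on their medians, and 93.2% (93 higher and 1272 lower) without shLuc replicate 1. Requiring both hairpins left 2615 genes, shDNMT1#1 alone called 1611, both hairpins as 1 group left 326, the hairpin as a random block left 31, the array SD as a covariate left 119, and leaving out shLuc replicate 1 left 1365 in all.

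**Figure D3:**
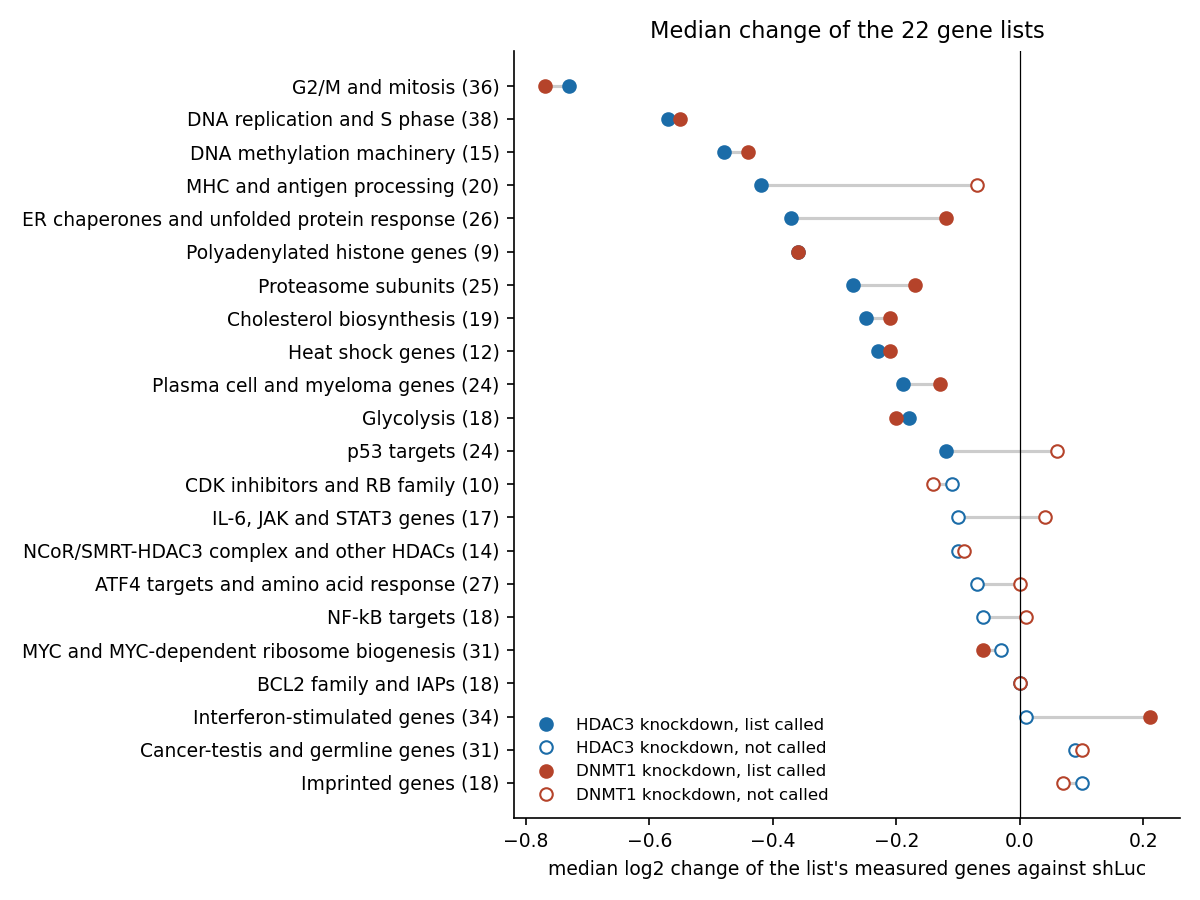
Median log2 change against shLuc (x axis) of the measured genes of each of the 22 fixed lists (y axis, number of genes in brackets), in HDAC3 knockdown (blue) and DNMT1 knockdown (red); filled points are lists called by camera at the preset correlation. The G2/M and mitosis list lies lowest in both, at -0.73 and -0.77.

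The knockdowns were then set against each other directly. The interferon-stimulated list was called higher in DNMT1 than in HDAC3 knockdown (adjusted p = 0.042 with an estimated correlation). The antigen presentation and endoplasmic reticulum lists were called higher at the preset correlation alone (adjusted p = 0.084 and adjusted p = 0.32 with an estimated correlation). TRIM22 differed most (2.40 ± 0.10 SE, n = 4 against 4), rising by 1.79 in DNMT1 knockdown and falling by 0.61 in HDAC3 knockdown. The rise was similar with shDNMT1#1 (1.74) and shDNMT1#2 (1.83). The fall came mostly from shHDAC3#1 (-1.11), with shHDAC3#2 at -0.11. RPN2 (1.64 ± 0.06), KLHL5 (1.44), GALNT3 (1.40) and the Golgi coat regulator ARFGAP3 (1.32) were also higher in DNMT1 knockdown. Against shLuc, RPN2 was at -2.98 with shHDAC3#1, the group whose ACTB difference was 1.00, and -0.56 with shHDAC3#2, KLHL5 at -2.87 and -0.50, GALNT3 at -2.83 and -1.03, and ARFGAP3 at -1.94 and -0.83. The lysosomal protein LAPTM4A (-1.65 ± 0.07), DNMT1 (-1.46 ± 0.09), BOLA3, which acts in iron-sulfur cluster assembly (-1.43), QSER1 (-1.11) and DENND6A (-1.06) were lower. The other QSER1 probe sets, all dimmer, lay between -0.31 and 0.02 in DNMT1 knockdown. LAPTM4A was lower with shDNMT1#2 (-2.42) and not with shDNMT1#1 (0.34, adjusted p = 0.0508) against shLuc. HDAC3 was higher by 0.81 ± 0.13 (adjusted p = 0.00017).

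Of the antigen presentation genes, 13 of 20 were higher in DNMT1 than in HDAC3 knockdown, 16 adjusted over the list alone, and none lower (median 0.33; camera, adjusted p = 4.5e-13; adjusted p = 0.084 with an estimated correlation). Of the endoplasmic reticulum genes, 17 of 26 were higher and 1 lower, or 18 and 1 adjusted over the list alone (median 0.30; adjusted p = 7.5e-12; adjusted p = 0.32 with an estimated correlation). Of the interferon-stimulated genes, 10 of 34 were higher and none lower, or 13 and 1 adjusted over the list alone (median 0.20; adjusted p = 1.7e-06), the one call that also held with an estimated correlation (adjusted p = 0.042 with an estimated correlation). Of the p53 targets, 8 of 24 were higher and 0 lower, or 10 and 2 adjusted over the list alone (adjusted p = 0.00015; adjusted p = 0.72 with an estimated correlation). Proteasome subunits were higher in 3 cases and lower in 1 of 25, or 5 and 1 adjusted over the list alone (adjusted p = 0.044; adjusted p = 0.96 with an estimated correlation; adjusted p = 0.058 with arrays centred on their medians). G2/M genes were lower in 8 cases and higher in 1 of 36, or 11 and 1 adjusted over the list alone (median -0.10; adjusted p = 0.00043; adjusted p = 0.96 with an estimated correlation). Against shLuc that list had medians of -0.19 with shHDAC3#1, -1.05 with shHDAC3#2, -0.44 with shDNMT1#1 and -1.09 with shDNMT1#2, which lie further apart within each target than the targets do. In the same order, the antigen presentation medians were -0.57, -0.23, 0.05 and -0.18, so the second hairpins lay close together. The endoplasmic reticulum medians were -0.47, -0.29, -0.04 and -0.11, and the interferon-stimulated ones 0.01, 0.02, 0.14 and 0.21. Those of the p53 targets were -0.19, -0.03, 0.02 and 0.03, and of the proteasome -0.31, -0.26, -0.11 and -0.29. For the difference between the knockdowns, all 6 lists had medians outside the central 95% of random lists of the same level. In all, 1897 genes differed, 1187 higher and 710 lower in DNMT1 knockdown. The balance turned with the hairpins taken: hairpin 1 of each target alone gave 1860 higher and 521 lower, and hairpin 2 alone 682 higher and 1129 lower. The hairpin numbers do not pair constructs of different targets, and hairpins of unlike number were not set against each other. With both hairpins as 1 group 29 genes differed, and with the hairpin as a random block 6. Of the 35 splits of the 8 knockdown arrays into 4 and 4, fitted on these arrays alone, the split by target called 17 genes, while the other 2 splits that keep hairpins whole called 196 and 186.

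Hairpins of 1 target were compared to see which changes differed between them. As the replicates of a hairpin may share 1 culture, an effect of the construct cannot be told apart from one of culture or infection. Between shHDAC3#1 and shHDAC3#2, the Wnt inhibitor DKK1 (2.36 ± 0.16 SE, n = 2 against 2), the nucleoporin NUP58 (2.33 ± 0.15) and the cold-inducible RBM3 (2.30 ± 0.13) were higher with the first. ERGIC1 (-2.53 ± 0.09), ARMC1 (-2.46 ± 0.11) and RPN2 (-2.42 ± 0.09) were lower. The shHDAC3#1 arrays had a mean ACTB difference between 3' and 5' of 1.00 against 0.74 in shHDAC3#2, a GAPDH difference of 0.52 against 0.355, and hybridization controls at 11.63 against 11.285. Between shDNMT1#1 and shDNMT1#2, the protease inhibitor CSTB (3.23 ± 0.08, 9.4-fold), AIDA (2.91 ± 0.12) and LPXN (2.83 ± 0.10) were higher with the first, and the plasma cell gene MZB1 (-2.20 ± 0.11), CXCL10 (-1.73 ± 0.14) and RND3 (-1.67 ± 0.12) were lower. In all, 2492 genes differed between the HDAC3 hairpins (742 higher and 1750 lower with shHDAC3#1) and 2365 between the DNMT1 hairpins (1659 higher and 706 lower with shDNMT1#1). After a further quantile normalization, 43.3% of the latter were lower in place of 29.9%. Across genes, which are not independent replicates, log2 changes correlated between hairpins with r = 0.588 for HDAC3 and 0.638 for DNMT1, against 0.5 for simulated unchanged hairpins with shared controls. Hairpins of different targets correlated with r from 0.58 (shHDAC3#1 and shDNMT1#1) to 0.718 (shHDAC3#2 and shDNMT1#2), and part of each value may come from the shared controls. The HDAC3 hairpins called 4834 and 2146 genes against shLuc, 1350 the same way and 78 in opposite directions, and the DNMT1 hairpins called 1611 and 5303, 1175 the same way and 45 in opposite directions. Hairpins of different targets shared from 919 (shHDAC3#2 and shDNMT1#1) to 2354 calls the same way (shHDAC3#1 and shDNMT1#2) and 21 to 84 in opposite directions. Independent lists would share 131.9 and 679.3 calls the same way in these 2 pairs, 333.8 between the HDAC3 and 235.4 between the DNMT1 hairpins. Calls were thus shared between targets as well as within them. The counts depend on how many genes each hairpin called, and the shared controls may add to them, so they do not measure how specific the sharing was. Root mean square distances between the hairpins' mean log2 values do not use the controls. By these, shHDAC3#2 lay nearer to shDNMT1#1 (0.211) and shDNMT1#2 (0.256) than to shHDAC3#1 (0.292). The shHDAC3#1 group lay at 0.29 from shDNMT1#1 and 0.319 from shDNMT1#2, and the DNMT1 hairpins lay 0.283 apart. These distances were not tested. Leaving out shHDAC3#1 replicate 1 left 1656 genes between the HDAC3 hairpins and leaving out shHDAC3#2 replicate 2 left 1635. Leaving out shDNMT1#2 replicate 2 left 1417 between the DNMT1 hairpins, and the array SD as a covariate left 670, of which 243 were higher and 427 lower with shDNMT1#1.

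The responses to the knockdowns overlapped. The genes that rose most in both were OSTM1 (1.84 in HDAC3 and 1.82 in DNMT1 knockdown), C11orf54 (1.24 and 1.36), RRP1B (1.35 and 1.13), CFL2 (0.79 and 0.86) and RNF149 (0.79 and 0.76). Those that fell most in both were UHRF1 (-1.68 and -1.61), AIDA (-1.44 and -1.81), the ubiquitin ligase subunit WSB1 (-1.42 and -1.42), the cytoskeletal regulator DPYSL2 (-1.41 and -1.43) and E2F8 (-1.30 and -1.67). The fall of AIDA was uneven: -2.2 with shHDAC3#1, -0.69 with shHDAC3#2, -0.35 with shDNMT1#1 and -3.26 with shDNMT1#2. Of the other WSB1 probe sets, that at a mean of 5.84 was at -1.26 and -1.21 and that at 5.5 at 0.23 and 0.26. In both, 287 genes rose, against 52.2 for independent lists, and 2050 fell, against 408.1. Opposite calls were made for 12 genes, against 307; among genes passing the test with each hairpin, the interferon-induced IFITM1 alone went opposite ways (-0.44 and 0.56), and it was named after its values were seen. Across genes, the log2 changes correlated with Pearson's r = 0.792, against 0.667 for simulated unchanged groups with shared controls, and with Spearman's rho = 0.76, against 0.647. The covariance was 0.0613, against 0.00732 in the simulation, a difference of 0.054, and 82.6% of genes had the same sign, against 73.2%. Both knockdowns were compared with the same 2 control arrays, and part of the excess may come from the shared controls. Genes were simulated independently and without variation between hairpins or cultures, so the simulation may understate how far the chance values range.

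**Figure D4:**
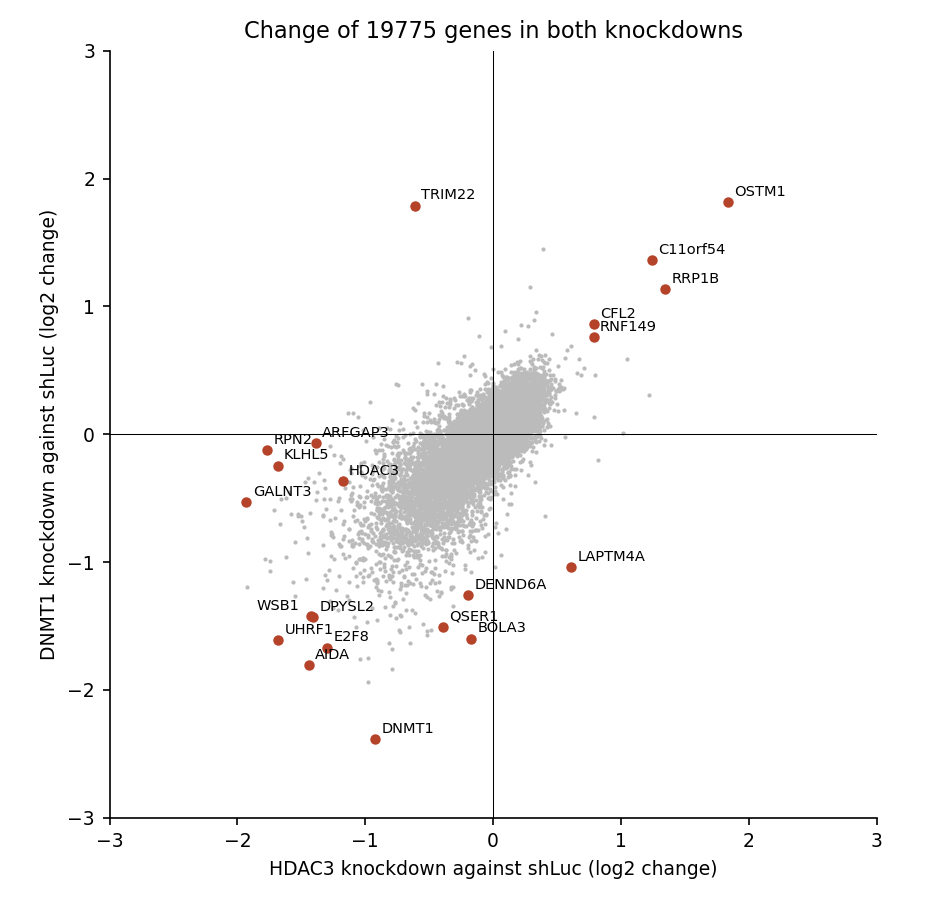
Log2 change against shLuc in HDAC3 knockdown (x axis) and DNMT1 knockdown (y axis) of 19775 genes, 1 grey point per gene; red points are the targets, the genes that changed most in both knockdowns and those that differed most between them. OSTM1 lies at 1.84 and 1.82, and TRIM22 at -0.61 and 1.79.

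Markers of other cell types stayed mostly outside the calls. No gene of the T and NK cell, monocyte and macrophage, or fibroblast lists was called in either knockdown. Their median log2 changes were 0.13, 0.15 and 0.12 in HDAC3 knockdown and 0.16, 0.11 and 0.10 in DNMT1 knockdown. Of the mature B cell list, FCER2 rose in HDAC3 knockdown (0.34, adjusted p = 0.0298) and CR2 fell in DNMT1 knockdown (-0.42, adjusted p = 0.00879), with list medians of 0.16 and 0.16. Of the epithelial and packaging cell list, KRT19 rose in HDAC3 knockdown (0.31, adjusted p = 0.0494), with list medians of 0.10 and 0.17. Of the erythroid list, HBB fell in both knockdowns (-0.38 and -0.64), with list medians of 0.06 and 0.06. These 4 genes were named after their values were seen.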

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

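The tests of unequal knockdown, of DNMT1 loss and of a low control level, and the array SD as a covariate, were chosen only after the results were seen.

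The 2 HDAC3 hairpins differed in 2492 genes and the 2 DNMT1 hairpins in 2365, by limma's test of the difference (adjusted p under 0.05). Which hairpin knocked its target down more was not settled, as neither target transcript passed the test between hairpins (adjusted p = 0.67 for HDAC3 and 0.14 for DNMT1). Whichever it was, a graded response to unequal knockdown would put the larger change of every gene under the same hairpin. This assumes that the change of each gene grows with the loss of the target, which was not tested. Among genes passing both between the hairpins and over them, with the larger p of both tests adjusted, the larger change lay under shHDAC3#1 in 776 and under shHDAC3#2 in 315, and under shDNMT1#1 in 141 and shDNMT1#2 in 903. The smaller side held 28.9% and 13.5%, above the 5% of false calls, with lowest values of 22.1% and 10.3% without each array in turn and with 34% and 16.4% after a further quantile normalization. Of the genes called between the hairpins and under each of them, 78 of 464 and 45 of 413 went opposite ways. If each gene's change grows with the loss of the target, these values argue against unequal knockdown as the whole cause, and leave open a part for it. The 5% of false calls covers the spread between these arrays only. A difference in the spread of values between arrays did not remove the differences, as a further quantile normalization gave 2817 and 2556 genes, although the array SD as a covariate left 670 genes between the DNMT1 hairpins. Effects of a hairpin's own sequence may remain as an untested explanation, as may a difference in culture or infection between hairpins. So may the RNA of shHDAC3#1, whose ACTB difference between 3' and 5' was 1.00 against 0.74 in shHDAC3#2. No biological explanation was tested.

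In HDAC3 and DNMT1 knockdown, more genes were lower than higher. After a further quantile normalization 55.6% and 53.8% of the called genes were lower, as a difference in the spread of values between arrays would give. A one-sided change in the cells could be evened out by the same step, so a biological source stays open.

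OSTM1, C11orf54, RRP1B, CFL2 and RNF149 were higher under all 4 hairpins. If loss of DNMT1 in both knockdowns set the size of the increase, it would be larger in DNMT1 knockdown, and the median ratio of the increases was 0.989. The genes were ranked by the smaller of their 2 changes, which draws this ratio to 1, so it decides nothing and the explanation stays open. A low level in the luciferase control may contribute: the range over the hairpins was 0.572 of their mean change, between the bounds set for and against it, and with 1 control hairpin the explanations cannot be told apart.

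The change differed between DNMT1 and HDAC3 knockdown in 1897 genes by limma's test of the difference. In fits of the 8 knockdown arrays alone, 3 of the 35 splits into 4 and 4 called at least as many genes as the split by target, which called 17, so chance is not excluded. The highest other split, shHDAC3#1 and shDNMT1#1 against shHDAC3#2 and shDNMT1#2, called 196, the split of shHDAC3#1 and shDNMT1#2 against the others called 186, and the 32 splits that break hairpins called 0. This points to a structure by hairpin, which cannot be told apart from one by culture, and 3 splits are comparable.

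Of 13522 probe sets without a single gene symbol, which entered no comparison, 564 were called in HDAC3 knockdown (138 higher and 426 lower) and 806 in DNMT1 knockdown (405 higher and 401 lower). The thr poly-A control had a signal of 8.51 in shHDAC3#1 replicate 1 and between 6.88 and 7.3 in the other 9 arrays.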

How the results depend on the processing

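The fit with the array SD as a covariate was chosen only after the results were seen. For changes whose cause does not follow from how the setting works, the cause was not tested. The array SD moves with the groups, so that fit has little left to estimate a knockdown from; leaving out an array takes replicates away, and in a group left with 1 array that array is assumed to vary like the others. In the lowest and the highest of 4 equal groups of genes by level, 86 and 1584 genes were called lower and 81 and 249 higher in HDAC3 knockdown, and 85 and 1474 lower and 252 and 294 higher in DNMT1 knockdown. The replicate numbers did not pair the arrays: replicate deviations correlated between groups from -0.34 to 0.27, and 2 of 10 arrays had their best match under their own number.

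With the array SD as a covariate, 114 genes were called in HDAC3 knockdown, 119 in DNMT1 knockdown and 670 between the DNMT1 hairpins, 7 lists were called in HDAC3 knockdown, HDAC3 there was at -0.98 and DNMT1 at -0.63, neither called. With both hairpins as 1 group the knockdowns had 362 and 326 genes and differed in 29. With the hairpin as a random block, at an estimated correlation of 0.35, they had 73 and 31 and differed in 6, and in HDAC3 knockdown HDAC3 (-1.18) and DNMT1 (-0.92) were not called; this setting counts the difference between hairpins as error. Requiring both hairpins gave 2415 and 2615 genes. Hairpin 1 alone gave 1611 genes for DNMT1 and a shared correlation of 0.58; hairpin 2 alone gave 2146 for HDAC3, a shared correlation of 0.718, and HDAC3 at -0.60 in DNMT1 knockdown. The replicate number as a block gave -0.36 for HDAC3 there (adjusted p = 0.031). Leaving out probe sets ending in x_at or s_at gave 2501 genes in HDAC3 knockdown, with fewer genes tested. An estimated inter-gene correlation left 0 lists in HDAC3 knockdown, 0 in DNMT1 knockdown and 1 between them, where 6, 4 and 3 had an unadjusted p under 0.05, and fry called 17, 12 and 7; in DNMT1 knockdown the filter on dim probe sets left 6 and a further quantile normalization 5.

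Leaving out each array in turn gave 1410 to 4598 genes in HDAC3 knockdown and 1365 to 4875 in DNMT1 knockdown, both lowest without shLuc replicate 1. It gave 1324 to 2341 genes between the knockdowns, 1635 to 2845 between the HDAC3 hairpins (lowest without shHDAC3#2 replicate 2; 1656 without shHDAC3#1 replicate 1) and 1417 to 2274 between the DNMT1 hairpins (lowest without shDNMT1#2 replicate 2). HDAC3 ran from -1.50 to -0.85 in HDAC3 knockdown and from -0.69 to -0.04 in DNMT1 knockdown, called there without shLuc replicate 2 (-0.69) and without shDNMT1#1 replicate 1 (-0.50). DNMT1 ran from -1 to -0.85 in HDAC3 knockdown and from -2.46 to -2.31 in DNMT1 knockdown. The shared correlation ran from 0.732 to 0.855, highest without shLuc replicate 2. Lists called ran from 9 to 14 in HDAC3 knockdown, 9 to 12 in DNMT1 knockdown and 5 to 6 between them.

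Of the named genes, the direction turned in 48 cases. With the array SD as a covariate these were, in HDAC3 knockdown, BIRC2 0.09, CDKN1B 0.06, IRF4 0.20, MAGEA1 0.04, MCL1 0.03, RB1 0.03, RCL1 0.03 and ZDBF2 0.14. In DNMT1 knockdown they were BIRC2 0.11, CDK4 0.00, DNAJA1 0.20, GPS2 0.05, H1-10 0.32, H1-2 0.22, HDAC1 0.06, MAGEA1 0.08, PGAM1 0.00, PSMD12 0.09, PSMD14 0.07, PSPH 0.17, SC5D 0.24, SEL1L 0.00 and ZDBF2 0.07. Leaving out probe sets ending in x_at or s_at, which takes another and often dim probe set of the gene (means of 2.86 for MBD2, 3 for SC5D and 4.59 for FAS), gave ASNS 0.13, FAS 0.05, HSPD1 0.17, MBD2 0.00, RCL1 0.20 and SC5D 0.02 in HDAC3 knockdown, and CDKN1C -0.01, FAS 0.18, HLA-DPB1 -0.06, IDI1 0.00 and SC5D 0.09 in DNMT1 knockdown. Hairpin 1 alone gave CDKN3 0.02, IRF4 0.08 and MYC -0.34 for HDAC3 and MYC -0.13 for DNMT1; hairpin 2 alone gave CDKN1A -0.01, ITGB7 0.03, MZB1 0.10 and PRDM1 -0.30 for HDAC3. In HDAC3 knockdown IRF4 was at 0.10 with the mean of probe sets and 0.18 after a further quantile normalization, PRDM1 at -0.01 with centred arrays. Leaving out each array there, MYC ran from -0.01 (without shLuc replicate 2) to 0.14 and PRDM1 from -0.12 (without shLuc replicate 2; -0.05 without shHDAC3#1 replicate 2) to 0.15. Over all 5485 values of 234 named results under alternatives, 4660 kept their direction and side of the threshold, 771 lost the call and 6 gained it. The settings that count the difference between hairpins as error went lower. With the hairpin as a random block, 25 named results kept both and 197 lost the call. With both hairpins as 1 group, 66 kept both and 156 lost the call.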

Other observations

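The tests of DNMT1 against the S phase genes were chosen only after the result was seen.

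Single genes of lists that were not called changed in both knockdowns. The NF-kB inhibitor TNFAIP3 was lower in HDAC3 (-1.09) and DNMT1 knockdown (-1.04). IL6ST, which encodes the signalling subunit of the IL-6 receptor, was also lower in each (-0.68 and -1.37).

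DNMT1 is needed at replication, so its fall in HDAC3 knockdown may belong to the lower level of S phase genes. With shHDAC3#2, DNMT1 (-0.65) lay at 0.06 from the median of the DNA replication and S phase list (-0.71), as such a fall would give, though a separate effect is not excluded. With shHDAC3#1, DNMT1 (-1.20 ± 0.12 SE) lay at -0.80 from the median (-0.40) and below each of the 38 genes of the list, whose 2.5th percentile was -0.86. DNMT1 was lower with shHDAC3#1 than with shHDAC3#2 (-0.55, adjusted p = 0.0027), while 21 genes of the list were higher with it and 1 lower. These values argue against a fall with the 38 genes of this list as the whole cause of the change with shHDAC3#1. They do not cover genes outside it. UHRF1 and HELLS, of the DNA methylation list, were at -2.06 and -1.11 with shHDAC3#1 and at -1.3 and -0.7 with shHDAC3#2. A fall of DNMT1 together with such genes is not excluded. The RNA of shHDAC3#1, whose ACTB difference was 1.00, and an effect of HDAC3 or of the hairpin on DNMT1 stay open as untested.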
